A study of Homo sapiens with 2 samples.

How the data were processed

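The data are ChIP-seq peak tables from HK-2 cells, with 1 library made with a p300 antibody and 1 control library. Per the labels' protocols, cells were grown in medium with 1 g/L glucose and 10% fetal bovine serum without treatment, sonicated chromatin was immunoprecipitated, and libraries of 200 to 500 bp were sequenced as paired reads of 150 bp. The control library is titled input, but its antibody field names an IgG isotype control. Groups were taken from the antibody field and the title, and the labels do not describe replicates.

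Each deposited table holds, per the file headers, a gene symbol, chromosome, start, end, strand, peak name, annotation, distance to the TSS and transcript for every peak, with positions and distances in bp. No column holds a read count, signal, fold or p-value. The peak caller, aligner and annotation tool are not given in the sources used here. The submitters' processing notes name CASAVA 1.4 and the build mm9, a mouse assembly. The positions were therefore checked against a human gene table of assembly GRCh38.p14: of 46483 peaks whose gene symbol matched, 99.9% were on the chromosome of that gene and 96.8% gave a TSS inside the gene or within 5 kb of it, so coordinates are given as GRCh38. That table was used for that check, for gene names, lengths and chromosomes, and for which genes neighbour each other; no coordinate of it is printed.

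Starts and widths were multiples of 200 bp, a start of 0 occurred, and neighbouring peaks were at least 800 bp apart. Positions were converted to 1-based by adding 1 to start and end. Distances were measured from the peak midpoint: for all 8715 transcripts with several peaks, midpoint and distance gave a single TSS, which was used as that transcript's TSS. Peak names ran to 54052, and 79 of these numbers were not analysed here. The table recorded under the p300 sample was found to be the non-intergenic part of the table recorded under the control sample. The planned comparison of a p300 list with a control list therefore became a comparison of nested lists. Whether the calls were made against the control library is not given in the sources used here. The tables follow an order that correlates with width (Spearman rho -0.68 across peaks), and what it was sorted on is unknown.

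A promoter peak was one with its midpoint within 1 kb of the TSS, and a distal one had its midpoint over 10 kb away. A wide distal peak can therefore still cover the TSS. Shares of peaks carry exact Clopper-Pearson 95% intervals, counts per Mb exact Poisson 95% intervals, and ratios of widths percentile intervals from 10000 bootstrap draws of peaks. Ratios of coverage and of density carry normal 95% intervals on the log scale. Peaks are not independent molecules or replicates, so these cover counting error only. With 1 library per group no test between groups was made and no p-value is given. Coverage around TSSs was computed on chromosomes 1 to 22 and X for coding transcripts named in the full list. Densities counting every peak around listed TSSs carry percentile intervals from 1000 bootstrap draws of transcripts. Both the coverage of TSSs and the density per chromosome were added after the tables had been seen. The interval of the correlation over bins is from 1000 bootstrap draws of bins. The span of a chromosome was taken as the end of its last peak.

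Gene lists were fixed before the data were examined: 19 lists covering TGF-β and epithelial-mesenchymal transition, matrix and adhesion, HIF machinery, HIF targets, proximal tubule, renal progenitor and injury, distal nephron, podocyte, endothelial, immune, epithelial junction and keratin, AP-1 and immediate-early, NF-κB, YAP and TEAD, p53 targets, coactivators, deacetylases, ribosomal proteins and neuronal genes. For each list, the share of members with a peak was placed among 10000 random lists of the same size, matched on gene length in 10 bins, and lists under percentile 2.5 or over 97.5 were called outside the random range. The number of lists outside by chance was counted by placing the random lists among themselves, since shares of small lists take few values. The design named all genes with a symbol as background. It was narrowed to 19335 protein-coding genes with a name after the tables and the first list results had been seen, because placeholder names in the gene table cannot match the symbols of the peak tables. The choice matters: 3 of 19 lists lay outside the range against coding genes and 9 against all genes with a symbol, and ribosomal proteins moved from percentile 1.14 to 38.05. Over both peak lists, 4 definitions of a peak and 3 kinds of matching, 24 tables of lists were computed, and 14 more as alternatives. Of 12849 symbols in the full list, 11055 matched a gene name or a unique older symbol. The procedure was tested on simulated data for the same 19335 genes: of 100 unchanged lists of 20 genes 5% fell outside the range, and of 100 lists whose odds of a peak were raised 4 times 78% lay above it. For unchanged lists of long genes 48% lay above the range without length matching and 2% with it. In these simulations each gene got a peak independently of its neighbours, with a chance set by gene length alone, and list genes were drawn at random. The observed peaks are uneven over the chromosomes. The simulated rates therefore need not hold for the fixed lists, above all for lists whose members lie close together.

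Genes are named by a rule set before the data were examined: EPAS1, HIF1A, EP300 and CREBBP; the 10 genes with the strongest promoter peaks and the 5 with the strongest distal ones; and in each list the 2 members with the strongest promoter peak, or any peak where the list had none. Width was used in place of strength, since no fold, height or significance was given. Other list members were named after their values were seen. Genes with a placeholder or clone name were left out of the rule, and some genes that the rule names are not reported here.

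Alternatives set beforehand were other promoter limits, fewer chromosomes, merged peaks, reciprocal overlap and unmatched random lists. Alternatives chosen after seeing the data were the full list, the promoter-TSS class, the wider peaks, the earlier part of the tables' order, random genes drawn within 100 neighbours on each side, the background as planned and subsets for coverage and density. Sequence motifs were not searched, since no genome sequence was used here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.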

Results

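Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed on HK-2 cells, an immortalised line of human kidney proximal tubule epithelium, grown in low-glucose medium with no treatment. One library was made with an antibody against p300 (EP300), a histone acetyltransferase that acts as a coactivator at promoters and enhancers. The other is titled as input, while its antibody field names a rabbit IgG isotype control. There was 1 library per group, so no value here has a replicate check, and intervals cover counting error only. The series title names EP300 and HIF2α, the protein product of EPAS1, in the setting of diabetic nephropathy, and the question taken from it was where p300 peaks lie relative to EPAS1 and to genes of fibrosis, hypoxia and tubular identity. The peak tables give positions and annotations but no read count, height, fold enrichment or p-value, so the sequencing depth behind each peak is unknown.

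The peaks, all of which carry EP300 in their names, were broad and lay mainly inside introns and between genes, far from transcription start sites (TSSs). The full list, recorded under the control sample, held 53973 peaks covering 283.3 Mb, and the shorter list, recorded under the p300 sample, held 25623 peaks covering 141.1 Mb. In the full list 28350 peaks (52.5%) were intergenic and 21580 (40.0%) intronic, whereas 1604 (2.97%) were annotated as promoter-TSS, 1460 (2.71%) as exonic and 979 (1.81%) as transcription termination sites (TTS). The median peak was 4 kb wide (quartiles 2.8 and 6.2 kb, widest 117.2 kb), and its midpoint lay a median of 60.5 kb from the TSS of its assigned transcript. Only 1.35% of peaks (728, exact 95% interval 1.25 to 1.45%) had their midpoint within 1 kb of that TSS, and 36.8% lay over 100 kb away.

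The lists of the p300 and the control sample were the same peak calls and cannot be set against each other as signal and background. Every one of the 25623 peaks in the p300 list occurred in the control list with the same name, position and annotation (100% overlap). The 28350 peaks found in the control list alone were all annotated as intergenic, and the p300 list held 0 intergenic peaks. The p300 list is therefore called the genic list below and the control sample's the full list. In the genic list, 719 peaks (2.81%, exact 95% interval 2.61 to 3.02%) lay within 1 kb of a TSS, assigned to 702 genes. All peaks are treated here as p300 peaks on the ground of their names alone, the intergenic ones included, which are recorded under the control sample only. No level of background in the control library could be given from these tables.

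Transcription start sites of protein-coding genes were covered by a peak less often than positions 10 kb into the transcribed side. Of 12040 coding transcripts named in the full list, 16.9% had their TSS inside a peak (exact 95% interval 16.2 to 17.6%), against 21.8% at 10 kb downstream, a ratio of 0.777 (95% interval 0.738 to 0.819). The share was 16.3% at 1 kb upstream, the lowest of the offsets computed, and the share at 100 kb upstream was 17.7%. Counted by midpoint to the assigned transcript, the 2 sides of the TSS differed. Downstream, 394 peaks per kb fell in the first kb (exact Poisson 95% interval 356 to 435) and 484.4 per kb between 5 and 10 kb (465 to 504). Upstream, 334 per kb fell in the first kb (299 to 372) and 239.4 per kb between 5 and 10 kb (226 to 253). The upstream difference came with the assignment of peaks to transcripts. By assignment, over coding and other transcripts, density in the first kb over that at 5 to 10 kb was 1.39 upstream. With every peak counted around all listed transcripts on chromosomes 1 to 22 and X, it was 0.926 upstream (bootstrap 95% interval 0.837 to 1.01) and 0.890 downstream (0.812 to 0.976). Around the coding TSSs alone it was 0.805 upstream (0.719 to 0.898) and 0.842 downstream (0.760 to 0.929). Coverage, which also uses every peak, likewise fell toward the TSS on the upstream side, from 19.3% at 10 kb. The width of promoter and distal peaks was not distinguishable with promoters taken as within 1 kb. In the genic list the median width was 4 kb both within 1 kb of a TSS and beyond 10 kb, a ratio of 1.00 (bootstrap 95% interval 0.905 to 1.05). With promoters taken as within 3 kb, an alternative set beforehand, promoter peaks were wider, with a ratio of 1.1 (1.05 to 1.15). The transcripts are only those to which at least 1 peak was assigned, so these shares are not those of all genes; peaks covered 9.33% of chromosomes 1 to 22 and X. This comparison was added after the tables had been seen.

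**Figure D1:**
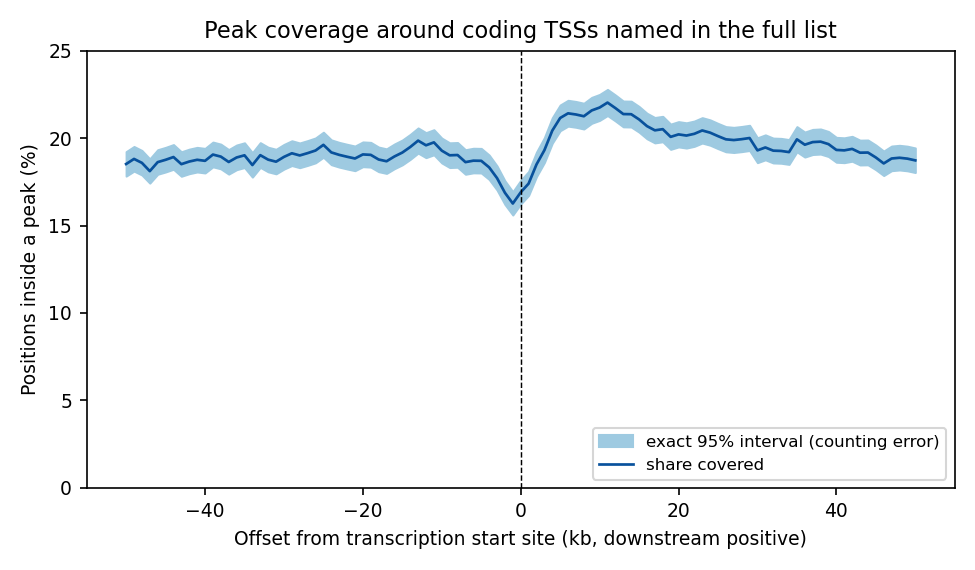
Share of positions inside a p300 peak (y axis, percent) by offset from the TSS of 12040 coding transcripts (x axis, kb, downstream positive); the line is the share and the band its exact 95% interval for counting error. The share dips to 16.3% at 1 kb upstream and is 21.8% at 10 kb downstream.

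At EPAS1, which encodes the hypoxia-inducible transcription factor subunit HIF2α, peaks were found upstream, inside and downstream of the gene, and none covered the TSS of either annotated transcript. The full list assigned 6 peaks to EPAS1, 3 of them in the genic list. All positions are on chromosome 2 of GRCh38. The upstream peak assigned to EPAS1, at 46285601 to 46294800, was 9.2 kb wide and annotated as intergenic. Its midpoint lay at -6.41 kb from the TSS of transcript ENST00000449347 and -7.20 kb from that of ENST00000263734. Farther upstream, intergenic peaks with midpoints at -39.5, -44.3, -61.1 and -96.0 kb from the latter TSS were assigned to other genes and are not among the 6. The 3 genic peaks lay at 46353201 to 46359200 in exon 4 of 7 of ENST00000449347, at 46367601 to 46373000 in intron 7 of 15 of ENST00000263734, and at 46380801 to 46386200 in its intron 15. A further 2 intergenic peaks lay downstream, at 46389801 to 46392200 and 46406801 to 46412400. The number of peaks at EPAS1 was high but not extreme for a gene of its length. It stood at percentile 81.9 of 1933 coding genes of similar length, whose median was 2 peaks, and at percentile 74.1 of 27 neighbouring genes of similar length, whose median was 3.

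**Figure D2:**
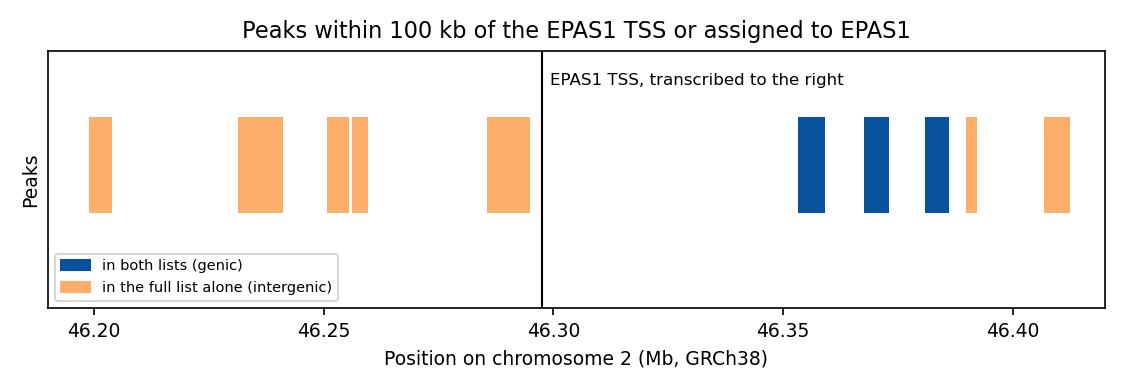
Peaks within 100 kb of the EPAS1 TSS or assigned to EPAS1, to scale on chromosome 2 (x axis, Mb, GRCh38); each bar is 1 peak, blue for the 3 genic peaks present in both lists and orange for intergenic peaks of the full list alone, and the line marks the TSS of ENST00000263734. No bar crosses the TSS.

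Other genes of the same pathway and of p300 itself differed in whether they held a peak. HIF1A, the paralogous hypoxia factor on chromosome 14, had 0 peaks in both lists, and so had CREBBP, the close relative of EP300, on chromosome 16. The median of their neighbours of similar length was also 0, and that of all coding genes of similar length was 1 for HIF1A and 3 for CREBBP. EP300 itself, on chromosome 22, had 2 peaks, against a median of 4 among 19 neighbouring genes of similar length (percentile 34.2) and of 2 among all coding genes of similar length (percentile 55.7). The tables list called peaks alone, so a count of 0 gives no upper limit on p300 signal at HIF1A or CREBBP.

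The widest promoter peaks, chosen by width because the tables hold no fold enrichment, lay at NAV1, CXorf49B, EDN3, GOLGA6A, SERHL2, FAM78A, CDH23, TMC2, WFDC5 and HTR3C. They were between 16.6 and 36.6 kb wide. The NAV1 peak covered 201605401 to 201642000 on chromosome 1, and that of EDN3, which encodes the signalling peptide endothelin 3, covered 59284401 to 59316000 on chromosome 20. TMC2 and WFDC5 are also on chromosome 20, CDH23, a cadherin gene, is on chromosome 10, and HTR3C, a serotonin receptor subunit gene, is on chromosome 3. The widest peaks with their midpoint over 10 kb from their TSS were at TBC1D3K (102.4 kb), RASA4 (74.8 kb), PRAMEF27 (69.4 kb), NPIPB15 (69.0 kb) and MUC20 (66.2 kb). These midpoints lay between 14.1 and 49.2 kb from the TSS, and the peaks were wide enough to cover it all the same. Those at PRAMEF27 and MUC20 were annotated as promoter-TSS. TBC1D3K, RASA4, PRAMEF27, NPIPB15, GOLGA6A and CXorf49B belong to families of near-identical genes, between which reads cannot be assigned with certainty, so their peaks are uncertain.

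Genes of proximal tubule and epithelial identity held a peak in the genic list more often than random genes of the same length, and ribosomal protein genes less often. Of 21 proximal tubule genes, 15 (71.4%, exact 95% interval 47.8 to 88.7%) had at least 1 peak, against a median of 42.9% in 10000 length-matched random lists (percentile 99.7). The widest were in intron 1 of SLC13A3, a dicarboxylate transporter gene (23 kb), and in intron 1 of HNF4A, which encodes a hepatocyte nuclear factor (15.4 kb), both on chromosome 20; LRP2, the gene for the endocytic receptor megalin, held 9 peaks and HNF4A 6. Of 17 epithelial junction and keratin genes, 12 (70.6%) had a peak against a random median of 41.2% (percentile 99.7), including KRT5 (13.2 kb) and CDH3 (12.8 kb), and 15 peaks fell at GRHL2, an epithelial transcription factor gene. Of the members with a peak, KRT5 and KRT8 are both on chromosome 12, and KRT14, KRT19 and JUP on chromosome 17. Random genes were drawn independently of each other, so members that lie close together can make this percentile too extreme. Of 30 ribosomal protein genes, 2 (6.67%) had a peak against 23.3% (percentile 1.14), RPS24 and RPL37A. The proximal tubule call was not kept in the full list (percentile 94.3), nor was the ribosomal protein call (percentile 13.7, and 10.2 with the wider or 12.6 with the earlier peaks), while the epithelial call was kept there (percentile 99.95) but lost with the wider peaks alone (97.2). Of 19 lists examined, 3 lay outside the central 95% of random lists, where 0.815 would by chance; in all, 24 such tables were computed over peak lists, peak definitions and matchings, and 14 more as alternatives. The ribosomal protein call also rests on the background: against all genes with a symbol, the background first planned, that list stood at percentile 38.05 and 9 lists lay above the range. These were the proximal tubule and epithelial lists (percentile 100 each), endothelial (99.9), podocyte (99.7), deacetylase (99.2), neuronal (99.2), distal nephron (99.0), HIF machinery (97.9) and immune (97.9) lists, so under that background the excess was not particular to renal or epithelial genes.

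**Figure D3:**
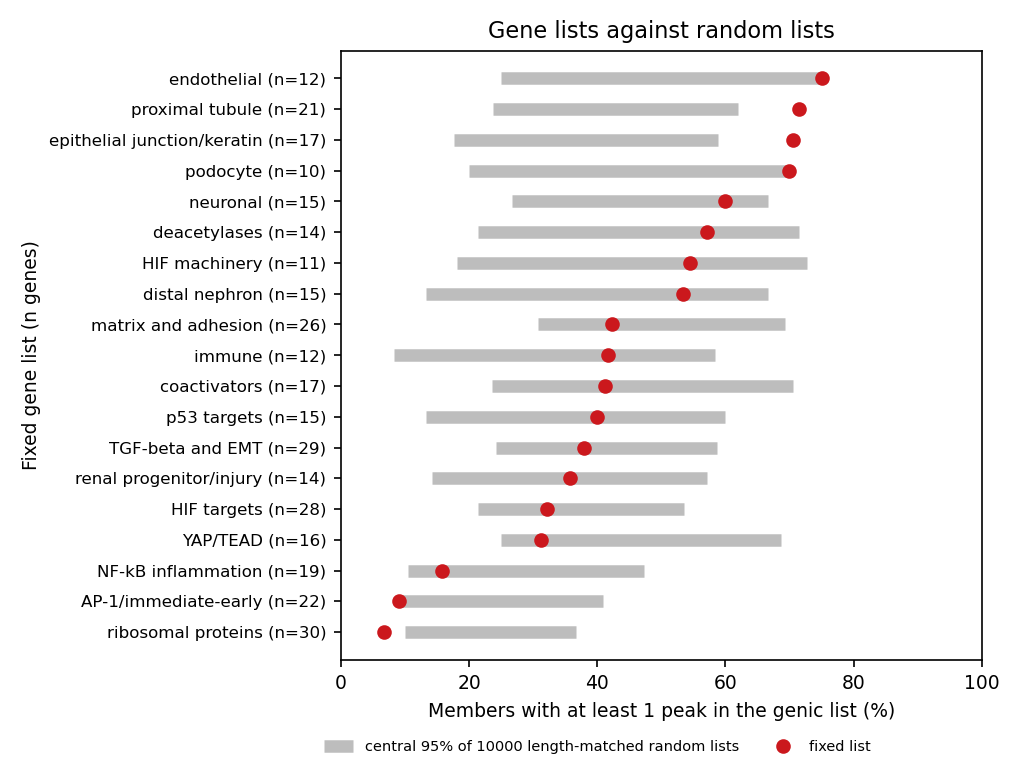
Share of each fixed gene list with at least 1 peak in the genic list (x axis, percent; red points) for 19 lists (y axis, n genes each), with the central 95% of 10000 length-matched random lists as grey bars. Proximal tubule (71.4%) and epithelial (70.6%) genes lie above their bars and ribosomal protein genes (6.67%) below.

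Fibrosis and hypoxia genes held peaks about as often as random genes of their length. Of 29 genes of transforming growth factor β signalling and epithelial-mesenchymal transition, 11 had a genic peak (37.9%, percentile 30.6), with the widest at BMP7 (20.8 kb, intron 2) and SKI (12.4 kb, intron 1). LTBP1, a latent TGF-β binding protein gene, held 12 genic peaks, and TGFB1, SMAD3, VIM and ZEB2 held 0 in either list. Of 26 matrix and adhesion genes, 11 had a genic peak (42.3%, percentile 21.4): COL5A1 held 12, COL1A1 held 1, and FN1, COL4A1 and ITGB1 held 0. Of 11 genes of the hypoxia-inducible factor machinery, 6 had one (54.5%, percentile 81.3, but 97.9 against the background first planned), with 14 peaks at EGLN3, a HIF prolyl hydroxylase gene, and 5 at HIF3A. Of 28 HIF target genes, 9 had one (32.1%, percentile 29.0): NDRG1 held 5, P4HA2 held 6 and VEGFA 1 (13 in the full list), whereas LDHA, PGK1, CA9 and ADM held 0.

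Genes of other cell types also held peaks, and whether their lists differed from the renal lists was not tested. Among 12 endothelial genes 9 had a genic peak (75%, percentile 96.8), with 8 peaks at VWF and 3 at PECAM1, and among 10 podocyte genes 7 had one (70.0%, percentile 95.7), with a peak of 10.2 kb at PODXL. The endothelial list passed the upper bound when random genes were drawn from neighbours (percentile 98.8) or without matching (99.4), and the podocyte list did in the full list (98.8), with the earlier peaks (99.5) and with the wider peaks (97.7). Of 15 neuronal genes, 9 had a peak (60.0%, percentile 85.4), with 33 peaks at RBFOX3 and 12 at GRIN2B. Immune genes (5 of 12, percentile 78.2, widest at CD8A and ITGAM), distal nephron genes (8 of 15, percentile 86.2, widest at SLC12A3 and SCNN1A) and renal progenitor or injury genes (5 of 14, percentile 52.1, widest at PAX2 and PROM1) lay within the random range. With the wider peaks alone the distal nephron list passed it (percentile 98.5).

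Stress-response and chromatin genes lay within the length-matched random range, though not under every alternative. Only 2 of 22 AP-1 and immediate-early genes had a genic peak (9.09%, percentile 4.95), ATF3 and EGR2, while 9 had one in the full list. Without length matching, an alternative set beforehand, this list stood at percentile 0.185 and the NF-κB list at 1.91, both below the range, and against the background first planned the deacetylases lay above it (99.2). NF-κB and inflammatory genes (3 of 19, percentile 17.2) had peaks at TNFAIP3, ICAM1 and SOD2. YAP and TEAD genes (5 of 16, percentile 14.5), p53 targets (6 of 15, percentile 69.2, widest at BTG2 and SESN2), coactivators and acetyltransferases (7 of 17, percentile 26.6, with 4 genic peaks at KAT6B) and deacetylases (8 of 14, percentile 84.3, with 26 peaks at HDAC4 and the next widest at HDAC7) were within the random range.

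Promoter peaks, with their midpoint within 1 kb of the TSS, were found at 8 members of the fixed lists. In the genic list these were COL5A1 (9.4 kb, midpoint 325 bp downstream of the TSS, 134637401 to 134646800 on chromosome 9), COL1A2 (2.8 kb, midpoint at -762 bp, 94392401 to 94395200 on chromosome 7), TNC, NDRG1 (4.4 kb), PECAM1 (2.4 kb), EGR2 (3 kb), AJUBA (5.4 kb) and CAMK2A (5.8 kb). The matrix and adhesion list, with 3 of 26 members (11.5%), was the only 1 of 19 lists outside the random range (percentile 99.2). By chance 0.424 lists would lie above the range, and with so few promoter peaks none could lie below it. The matrix list fell within the range when a promoter reached 3 kb from the TSS (percentile 89.8), where the neuronal list (4 of 15, percentile 99.4) and the endothelial list (3 of 12, percentile 98.4) lay above it, or when the promoter-TSS class of the tables was used (percentile 92.5). With the limit of 1 kb the other 13 lists had no member with a promoter peak. The number depends on the definition: 26 members in 13 lists had one within 3 kb. By the promoter-TSS class it was 20 members in 13 lists.

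Peaks were distributed very unevenly over the chromosomes. Chromosome 20 held 42.6 peaks per Mb (exact Poisson 95% interval 41.0 to 44.2), with 33.6% of its span inside a peak and 74.8% of its coding genes assigned at least 1. Chromosome 17 followed with 32.3 peaks per Mb. Chromosome 13 held 1.14 peaks per Mb (0.951 to 1.35), and 18 (2.01), 21 (2.14), X (2.68), 11 (3.06), 15 (4.46) and 14 (7.22) were also sparse. The first 15 Mb of chromosomes 13 and 14 and the first 20 Mb of chromosome 15 held 0 peaks. These stretches count in the spans and lower the densities given. The ratio of chromosome 20 to 13 was 37.4 (95% interval 31.4 to 44.6), but it was 80.5 with the wider peaks and 209 with the earlier peaks of the tables' order, so its size depends on which peaks are counted. Densities also changed within chromosomes: chromosome 9 had 111 peaks in its first 80 Mb and 2305 in the rest (1.39 against 38.4 per Mb), chromosome 10 had 127 in its first 40 Mb and 3427 beyond, and chromosome 8 had 204 in its first 45 Mb and 2886 beyond. Of 1279 coding genes on chromosome 11, 15.6% were assigned a peak; WT1, CD44, LDHA, ADM, TEAD1 and YAP1, all on this chromosome, had 0. The positions at which chromosomes 8, 9 and 10 were divided were chosen on the same peaks, as those with the highest Poisson likelihood, so the differences between their parts are not independent of that choice.

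**Figure D4:**
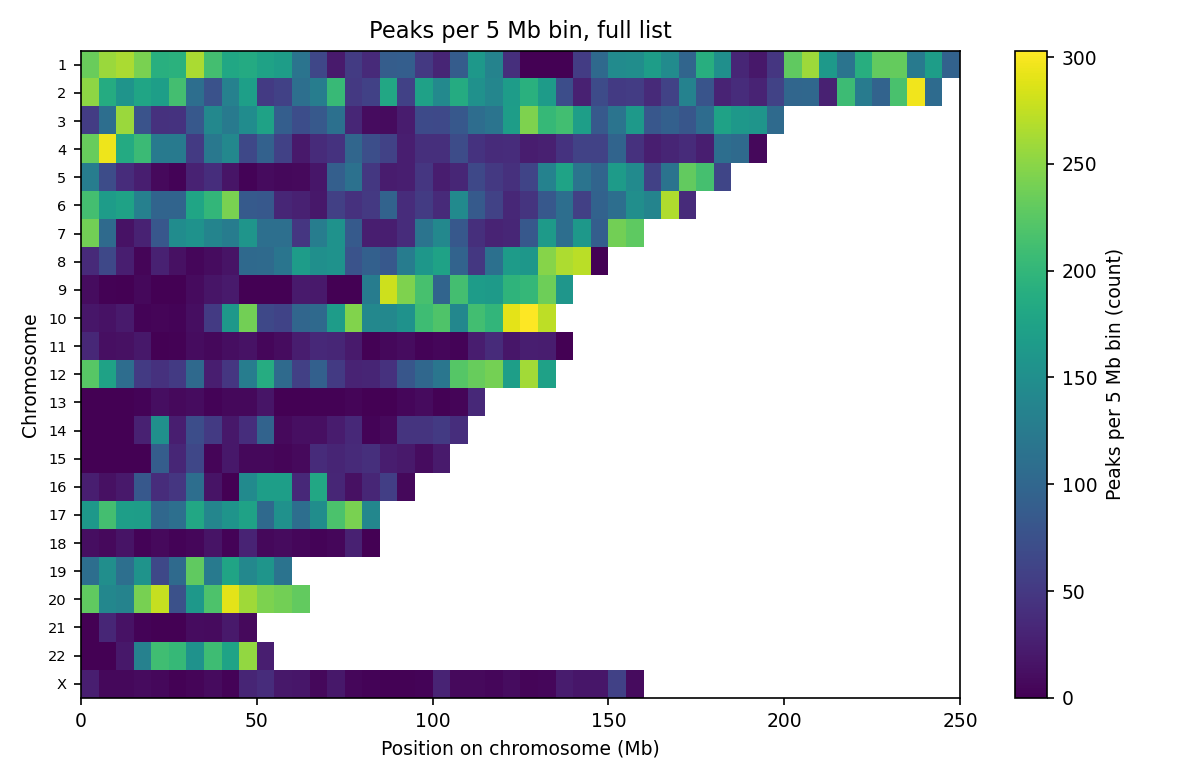
Number of peaks of the full list in each 5 Mb bin (colour, count) by position (x axis, Mb) on chromosomes 1 to 22 and X (y axis). Chromosomes 11, 13, 18, 21 and X are dark throughout, chromosome 20 is bright, and chromosome 9 changes from dark to bright at 80 Mb.

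Long genes held a peak more often than short ones. Of 10 bins of coding genes by length, the shortest, with a median length of 1.82 kb, had a genic peak at 10.8% of its genes, and the longest, with a median of 256.6 kb, at 68.6%. Across all 19335 coding genes the share was 38.1% in the genic list and 50.9% in the full list.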

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

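No test was run for these values; they were picked out, after the tables were seen, because they lie in the 28350 intergenic peaks that the list recorded under the p300 sample leaves out. The control sample gives no level to compare them with, so the mark was more than the 3 counts that a count of 0 allows. That mark is only a convention. The genic list holds 0 intergenic peaks by construction, so passing the mark does not make a count unusual. At EPAS1 itself, 3 of its 6 peaks are intergenic. Of the 343 genes in the fixed lists, 57 had intergenic peaks alone, and 20 of those had more than 3. Apart from EPAS1, list genes with a genic peak as well were not flagged, however many intergenic peaks they had. Among these, RPS24 had 38 peaks with 1 genic, PODXL 20 with 3 genic and SOD2 14 with 1 genic.

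Among transcription factor genes, SOX9 was assigned 30 intergenic peaks, KLF4 17, CITED2 14, JUN 9, KLF10 8, NEUROD6 7, and SOX4, SNAI2, SKIL and MYC 4 each. The SOX9 peaks spread over 783.2 kb of chromosome 17, from 71569601 to 72352800, and the nearest lay 7.82 kb from the TSS. Among the other genes CITED2 had 14, COL12A1 9, and ANKRD1 and the β-catenin gene CTNNB1 7 each. AMOTL2 and the glucose transporter gene SLC2A1 had 6 each, CD24 and F3 5 each, and SKIL and RPL11 4 each. The median of neighbouring genes of similar length was 1 peak for KLF4 and 0 for SOX9 and CITED2. Among those neighbours SOX9 stood at percentile 95.2, CITED2 at 92.9 and KLF4 at 88.9. The neighbours were so few, with the gene itself counted among them, that even the highest count could not pass the upper bound used for the lists. That bound therefore cannot decide whether these counts are unusual. Intergenic peaks were assigned to a gene by position, so these counts also grow with the distance to the next gene.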

How the results depend on the processing

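The values given for the full list, the promoter-TSS class, the wider or earlier peaks, neighbouring genes, the wider background, and all alternatives for TSS coverage and chromosome density were chosen after the data were seen. In 44 recomputations of the main results, 26 values stayed within their interval or within 1.5 times, and 18 moved. Several of the 26 could not move, because the overlap of nested lists is complete and there were no peaks to merge. Taking the full list in place of the genic list gave 53973 peaks, a promoter share of 1.35% and 6 peaks at EPAS1, by construction. A promoter limit of 3 kb gave a share of 7.23%, 1809 genes, a width ratio of 1.1 (interval 1.05 to 1.15) and 2 lists outside the random range, and the promoter-TSS class gave 6.26%, 1571 genes and 0 lists. For any peak, 6 lists lay outside without length matching and 9 against the background of all genes with a symbol, which was the one planned. The earlier part of the tables' order left 1 peak at EPAS1. The coverage ratio at TSSs was 0.825 with all annotated transcripts and below 1 under every alternative run. The ratio of the densest to the sparsest chromosome was 53.2 for genic, 29.4 for intergenic, 80.5 for wider and 209 for earlier peaks, always chromosome 20 against 13, and why it moved between these settings was not tested. Of 266 recomputed list percentiles, 241 kept their side of the bounds, 17 passed a bound and 8 fell back within them. The 241 say little about how stable the calls are, because most lists lay within the bounds from the start. Only the 3 lists called for any peak and the 1 called for promoter peaks could fall back. Of the 8 percentiles that did, 6 were for any peak and 2 for promoter peaks. Restricting to chromosomes 1 to 22 and X, merging peaks within 500 bp and asking for 50% reciprocal overlap moved none of these values beyond those bounds; the merge joined nothing. Planned thresholds on score or fold, summit distances, motif windows and promoters from the reference were not run. The peak tables hold no score or summit, no genome sequence was used, and the human gene table gave no strand. No paired analysis was possible because each group has 1 library and the labels give no replicate number. Depth limits every count, and its size is unknown.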

Other observations

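The tests on gene content, on narrow peaks, on the widest peaks within chromosomes and on gene families were chosen after the result was seen. Outside the fixed lists, genes of chosen families of the general cell machinery were assigned peaks less often than genes of chosen tissue-restricted families. Of 367 genes of the proteasome, respiratory chain, mitochondrial ribosome and import, translation initiation, RNA polymerase II, spliceosome, exosome, COP9 signalosome and ubiquitin conjugation, 126 had a peak in the full list (34.3%, exact 95% interval 29.5 to 39.4%), below all 10000 random lists matched on length among neighbouring genes (mean 44.0%). Of 497 genes of claudin, mucin, ion channel, serpin, ADAMTS, transporter, receptor, cadherin, WNT and related families, 285 had one (57.3%, interval 52.9 to 61.7%), above the random mean of 51.8% (percentile 99.8). Matched on length alone, the second group stood at percentile 90.6 in the full list, inside the random range. In the genic list it stood at 97.9, just above it. The families were picked after the fixed lists had shown the pattern and after a scan of 102 symbol families of at least 20 genes. In that scan 7 families, among them CYP, KRT and CCL, lay above the range of neighbouring genes and 8, among them ZNF, TAF and DDX, below. Restricted families did not all rank high. Olfactory receptor (OR) genes (25.8% of 392) stood at percentile 35.0 among neighbours and 0.115 on length. Keratin-associated protein (KRTAP) genes (10.6% of 94) stood at 61.0 and 0.025. Nor were all families of the general machinery low among neighbours, with COX at 35.45, UBE at 24.2 and EIF at 13.15. Genes of a family can lie side by side, which independent draws do not keep, so these percentiles can be too extreme. Solute carriers, part of the restricted group, stood at percentile 96.8 among neighbours in that scan. Without them, 253 of 448 restricted genes (56.5%) had a peak, at percentile 98.8 among neighbours and 79.4 on length alone.

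A hypothesis is that the peaks favour tissue-restricted genes beyond gene length and location, and it stays open. With neighbour matching, the difference between the groups' excesses over random was 15.2 percentage points, made up of -9.63 for the general machinery and 5.56 for the restricted families. The families were chosen after the pattern had been seen in the same peaks, so this value restates the pattern and is no independent test of the hypothesis. The result may also reflect local sequence composition, which was not tested.

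The uneven density over chromosomes is the pattern most in need of a second look. The number of coding genes is not enough as a cause: peaks per coding gene still differed 16.2-fold between chromosomes. DNA dosage of the cell line left in the peak calls would act on genic and intergenic DNA alike, and over 5 Mb bins within chromosomes the counts of both kinds of peak ranked alike (Spearman rho 0.645, bootstrap 95% interval 0.584 to 0.702, 619 bins, which are not independent). That value is consistent with unequal copy number, as are whole chromosomes and long blocks with few peaks. Regional differences in p300 occupancy predict the same value and cannot be told apart from dosage here, because no read count of the control library was used. Bins without any peak were kept, such as those in the first 15 Mb of chromosome 13. They rank alike for both kinds of peak whatever the cause, and whether reads can be placed in them is not known here. These bins can therefore raise rho.

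Peak density near TSSs was no higher than at 5 to 10 kb when every peak was counted (0.805 times upstream and 0.842 times downstream of coding TSSs). Around all listed transcripts it was 0.926 times upstream, with a 95% interval of 0.837 to 1.01, and 0.890 times downstream. Wide peaks could blur positions and hide a 2-fold excess. Among 6315 peaks at most 2 kb wide no such excess was seen with every peak counted. The ratio for them reached at most 1.18 on either side (95% interval 0.890 to 1.49, upstream of all listed transcripts). That holds for narrow peaks only and leaves open whether positions are blurred within the wider ones, which are other peaks. Narrow peaks counted to their assigned transcript alone gave 2.09 upstream (1.51 to 2.90), and counting every peak was chosen after that value was seen, because peaks assigned to other transcripts are missed by it. Counting to the nearest listed TSS of any transcript put 927 peaks within 1 kb in place of 728, a ratio of 1.27, also short of its mark. Weak enrichment in the library and a real scarcity of p300 at these promoters stay open, and neither was tested.

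The widest peaks of each chromosome lay at genes with near-identical copies more often than other peaks did (40 of 526, 7.60%, against 0.858%), but 12 of the families were listed because they had been noticed among the widest peaks. The 24 families not so noticed held 8 of the 526, a ratio of 3.22 to their share of the other peaks (95% interval 0.607 to 8.5 from resampled families), and 4 of the 8 were at SERF1 genes, so dense chromosomes as a cause are not excluded. Reads shared between near-identical gene copies are a candidate explanation, but 260 peaks at other such families had the same median width as the rest, 4 kb, a ratio of 1.00 (95% interval 0.9 to 1.1). That interval reaches the bound of 1.1 set beforehand, which keeps the explanation open, and no biological explanation was tested.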
